A study of Rattus norvegicus with 23 samples.

How the data were processed

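Total RNA from primary rat hippocampal neurons was extracted with Trizol and an RNeasy column with DNase, checked on a Bioanalyser, amplified and labelled with biotin, and hybridized to Illumina rat BeadArrays, per the labels. The deposited table without normalization holds, per the file headers, the intensity of each of 22523 probes on a linear scale and its detection p-value, which ranks the probe among negative control beads. It has 24 array columns. One array, XL42 replicate 1, was left out by the authors as an outlier, has no sample record and was not used here, which left 23 arrays in 9 groups of 2 or 3. The deposited values of the authors are log2 intensities that were quantile-normalized over the 23 arrays. They were recomputed from the table without normalization, with a largest difference of 5e-09.

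Intensities were background-corrected from the detection p-values, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3 with an offset of 16, with tables read by the R package data.table (version 1.17.8). The platform lists 1 gene symbol for 13793 probes and none for 8730. Symbols were matched to a current gene table of the GRCr8 assembly, used for names only: 13757 probes matched, 36 kept the platform's symbol and 4 symbols were updated. Probes with a detection p-value under 0.05 on at least 2 arrays were kept, and each gene was represented by its probe of highest mean, which gave 9258 genes, 196 of them with more than 1 probe that could have been used. Among 149 calls, over all comparisons, of 54 genes with another such probe, the other probe had the opposite sign in 18, of which 0 had an unadjusted limma p under 0.05, and the same sign at an unadjusted p under 0.05 in 71. A gene below background on every array of one group is given as a bound, at least so many fold, against the lowest intensity detected on those arrays, on the background-corrected scale. Array precision depends on the number of arrays, since no counts are involved.

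All arrays entered a limma fit with 9 group means and a spread per gene shared by all groups, with 14 residual and 4.8 prior degrees of freedom. There were 23 comparisons: each Aβ preparation against the scrambled peptide of its length, against control and, for cross-linked and fibrillar Aβ, against low molecular weight Aβ, the lengths against each other, each scrambled peptide and their mean against control, and the mean of the 6 Aβ groups against the mean of the scrambled groups. P-values were adjusted by Benjamini-Hochberg over the genes tested with a threshold of 0.05, and a moderated F test asked for any difference among groups. The named genes of a comparison were the 10 largest rises and 10 largest falls among genes that passed and whose arrays did not overlap, and up to 3 members of each list that passed. Where fewer than 5 genes passed all were named, and where none passed those of smallest p. App, Mapt, Gfap, Aif1, Fos and Hmox1 could be named whatever their result, and Mapt was not among the genes tested. Fewer are printed where a comparison adds little.

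The 21 gene lists were immediate early, unfolded protein and integrated stress, heat shock, oxidative stress (Nrf2), cholesterol synthesis, p53 and apoptosis, inflammatory (NF-kB), interferon, synaptic, oxidative phosphorylation, glycolysis and hypoxia, proteasome, ribosomal protein, lysosome and autophagy, amyloid and tau metabolism, cell cycle, and markers of neurons, astrocytes, microglia, the oligodendrocyte lineage, and vascular cells and fibroblasts. They were tested with camera of limma at a preset correlation of 0.01 and adjusted over lists within each comparison, and each call was tested again with an estimated correlation. Groups, comparisons, lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated.

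The alternatives were no background correction, median scaling, the values normalized by the authors, no detection filter, a stricter filter (detection p-value under 0.01 on at least 3 arrays), the replicate number as a block, only the groups compared in the fit, an estimated correlation for the lists, and each array left out in turn. One further alternative, leaving out the arrays above 10 on the second principal component, was added after the data were seen. Other splits of the samples were fitted where groups held at least 3 arrays. The fit was tested on simulated data built for 9258 genes: for F42 vs S42 it recovered 75.9% of changes of log2 1 and 99.4% of changes of log2 2, with 5.2% of calls wrong. For XL42 vs S42 it recovered 65.5% and 98.0%, with 5.7% of calls wrong, and for F40 vs S40 69.7% and 98.8%, with 5.3% wrong. The simulated noise was independent between genes and arrays. In the real data, 1 leading axis held 28.7% of the variance within groups, so the share of wrong calls there may differ.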

Results

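Gene expression was measured on Illumina rat BeadArrays in primary hippocampal neurons from Sprague Dawley rats. The neurons were exposed to amyloid-β (Aβ), the peptide that accumulates in Alzheimer's disease plaques, in 3 states of assembly and 2 lengths. The groups were untreated neurons (control, 3 arrays), low molecular weight Aβ40 (T40, 3) and Aβ42 (T42, 3), cross-linked oligomers of Aβ40 (XL40, 3) and Aβ42 (XL42, 2), fibrils of Aβ40 (F40, 2) and Aβ42 (F42, 3), and scrambled peptides of each length (S40, 2, and S42, 2). Control arrays also carried bright markers of astrocytes and fibroblasts, such as Gfap and Col1a2 (mean log2 14.63 and 13.71). Untreated neurons below therefore stands for whole untreated cultures, and changes are not assigned to a cell type. Dose and exposure time were not given in the sources used here. The labels do not say whether replicates came from separate cultures or animals, so the p-values measure the spread between these samples. The mean raw intensity per array ran from 679.2 on S40 replicate 1 to 1185 on T40 replicate 2. Between 10221 and 11650 probes per array were detected, 45.4 to 51.7% of the 22523 on the array. The number of arrays limits the precision.

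Arrays with fibrils stood apart from those of every other treatment. The first principal component held 44.9% of the variance and placed the 5 fibril arrays between 30.6 and 48.5. The XL40 arrays lay at 4.4, 6.3 and 14.6, and the remaining groups had negative values. The second component held 16.3% of the variance and did not follow the groups: S40 replicate 1 had the highest value, 35, and XL40 replicates 2 and 1 followed with 25.8 and 25.1. Among 9258 genes tested, 1085 differed among the 9 groups by the moderated F test of limma, and 1905 did so without S40 replicate 3. Log2 fold changes below carry the standard error of limma's fit, and p-values are two-sided. Fold changes are on the background-corrected scale: without background correction, 36 of the 94 list medians called over all comparisons were more than 1.5 times smaller, and none changed sign. Each gene named for the size of its change had arrays that did not overlap between the groups compared.

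**Figure D1:**
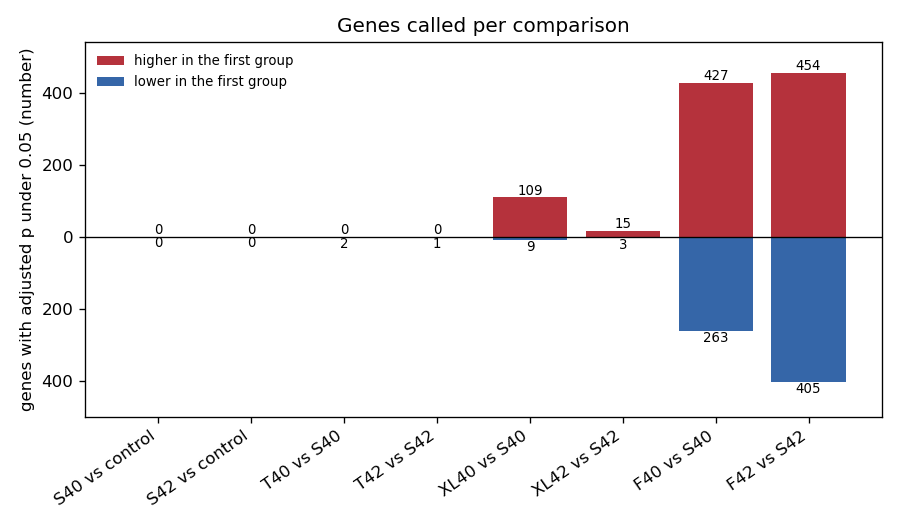
Number of genes higher and lower at an adjusted p under 0.05 (limma, 9258 genes tested) in each comparison. The fibril comparisons hold 690 (F40 vs S40) and 859 (F42 vs S42) genes, the cross-linked ones 118 (XL40 vs S40) and 18 (XL42 vs S42), and S40 and S42 against control 0.

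Scrambled peptides moved no single gene past the threshold against untreated neurons, a comparison that asks whether these control peptides alter expression themselves. The genes of smallest p with S40 were Tmem39a, which encodes a membrane protein of autophagy, at −0.93 ± 0.17, Tox, a DNA-binding factor, at 0.95 ± 0.20, and the activity-induced transcription factor Fos at 0.93 ± 0.20. None of these passed (adjusted p = 0.257). With S42, Pde12 (a mitochondrial RNA deadenylase) at −0.72 ± 0.15 and Daw1 at 0.94 ± 0.21 came closest (adjusted p = 0.513). The inflammatory genes kept medians of −0.15 with S40 (adjusted p = 0.433) and −0.14 with S42 (adjusted p = 0.203). By limma, 0 genes passed in S40 vs control, with 969 at an unadjusted p under 0.05, and 0 passed in S42 vs control, with 428. The mean of the 2 scrambled groups against control also gave 0, with 629 at an unadjusted p under 0.05. Its genes of smallest p were Sdc3, a heparan sulfate proteoglycan, at 0.95 ± 0.20, and Plekhh3 at −0.76 ± 0.16 (adjusted p = 0.33). The gene list test (camera) called a pair of lists in S42 vs control. Cell cycle genes had a median of −0.16 (adjusted p = 0.0181, adjusted p = 0.594 with an estimated correlation) and cholesterol synthesis genes a median of 0.19 (adjusted p = 0.013, adjusted p = 0.565 with an estimated correlation). S40 vs control rested on S40 replicate 3: without it, S40 replicate 1 alone gave 450 genes, 156 higher and 294 lower, and the mean of the scrambled groups gave 1.

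Low molecular weight Aβ lowered Egr1 and Fos, transcription factors that neurons induce when active, relative to scrambled peptide. In T40 vs S40, Egr1 fell by 1.43 ± 0.15 on the log2 scale (adjusted p = 0.000179) and Fos by 1.60 ± 0.20 (adjusted p = 0.00076). Fos with S40 lay above control without passing, which adds to its fall in T40 vs S40. In T42 vs S42, Egr1 fell by 1.01 ± 0.15 (adjusted p = 0.028), and the change of Fos, −0.96 ± 0.20, did not pass (adjusted p = 0.281). The 16 immediate early genes tested shifted down as a group, with a median of −0.28 in T40 vs S40 (adjusted p = 1.92e-06, adjusted p = 0.00682 with an estimated correlation) and −0.29 in T42 vs S42 (adjusted p = 2.44e-06, adjusted p = 0.00733 with an estimated correlation). With genes that lay below background at their bound, these medians were −0.11 and −0.17, and without background correction they were −0.18 and −0.13. Adjusted over the list alone, 6 of these genes were lower with T40 and 4 with T42. Inflammatory genes had a median of 0.09 in both comparisons (adjusted p = 0.772 and adjusted p = 0.703). Ribosomal protein genes had a median of −0.11 in T40 vs S40, or −0.32 with median scaling, a call that did not hold (adjusted p = 0.0493, adjusted p = 0.562 with an estimated correlation). Egr1 and Fos were the 2 genes that passed in T40 vs S40, and Egr1 the 1 gene in T42 vs S42. With only the groups compared in the fit, both counts were 0. The T40 count was 1 without S40 replicate 1, where Fos, at −1.35, no longer passed, and 621, 400 higher and 221 lower, without S40 replicate 3. The T42 count was 0 without any one of T42 replicate 2, T42 replicate 3, S42 replicate 1 or S42 replicate 3, and 2 without T42 replicate 1.

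Against untreated neurons, T40 changed no single gene past the threshold, and T42 raised Txnip, an inhibitor of thioredoxin that responds to glucose. Txnip rose by 0.94 ± 0.14 with T42 (adjusted p = 0.0238). Egr1 with T40, at −0.78 ± 0.14, missed the threshold (adjusted p = 0.196), a smaller fall than against S40. The immediate early genes were again lower as a group, by a median of −0.24 with T40 (adjusted p = 4.32e-08, adjusted p = 0.00234 with an estimated correlation) and −0.22 with T42 (adjusted p = 9.89e-06, adjusted p = 0.0114 with an estimated correlation), which were −0.11 and −0.18 without background correction. Adjusted over the list alone, 5 were lower with T40 and 3 with T42. Cholesterol synthesis genes had a median of 0.14 with T40 (adjusted p = 0.0147, adjusted p = 0.387 with an estimated correlation) and 0.13 with T42 (adjusted p = 0.0141, adjusted p = 0.336 with an estimated correlation). With T42, synaptic genes had a median of 0.24 (adjusted p = 0.00497, adjusted p = 0.22 with an estimated correlation) and cell cycle genes one of −0.24 (adjusted p = 0.00114, adjusted p = 0.505 with an estimated correlation). By limma, T40 vs control gave 0 genes, with 318 at an unadjusted p under 0.05, and T42 vs control gave 1. The call of Txnip was lost without any one of control replicate 1, control replicate 2, control replicate 3 or T42 replicate 3, each leaving 0 genes, and also without T42 replicate 2, where Txnip stood at 0.85. The count was 2 without T42 replicate 1.

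Cross-linked Aβ40 oligomers raised chemokines and other inflammatory genes strongly. Against S40, Ccl20, a chemokine that attracts lymphocytes and dendritic cells, rose by 6.12 ± 0.47 (adjusted p = 2e-07), and Lcn2, an iron-binding protein of the acute phase, by 5.89 ± 0.32 (adjusted p = 1.6e-09). Ccl2, which attracts monocytes, rose by 4.93 ± 0.40 (adjusted p = 2.98e-07), the neutrophil chemokine Cxcl1 by 4.47 ± 0.42 (adjusted p = 1.45e-06), and the copper-binding acute-phase gene Cp by 3.47 ± 0.40 (adjusted p = 2.14e-05). Genes that lay below background with S40 rose by at least 54.5-fold (complement factor Cfb), 18.7-fold (the matrix protease Mmp3), 13.4-fold (Ccl7) and 6.87-fold (the innate immune receptor Tlr2). Interferon-induced genes rose too, among them Mx1, an antiviral GTPase, by 2.90 ± 0.37 (adjusted p = 8.02e-05), Gbp2 by 2.57 ± 0.27 (adjusted p = 8.21e-06), and Ifit1 by at least 3.63-fold. Egr1 fell by 1.62 ± 0.15 (adjusted p = 1.71e-06), Fos by 1.54 ± 0.20 (adjusted p = 9.49e-05) and Egr2 by 0.69 ± 0.13 (adjusted p = 0.00725). Against control the fall of Egr1 was smaller, though it passed there too. Phlda3, a p53 target that restrains Akt signalling, rose by 1.35 ± 0.16 (adjusted p = 4.67e-05), and the mitochondrial antioxidant enzyme Sod2 by 0.92 ± 0.20 (adjusted p = 0.0177). The call of Sod2 was lost without any one of XL40 replicate 2 (0.75), XL40 replicate 3 (0.81), S40 replicate 1 (0.82) or S40 replicate 3 (1.02), and that of Egr2 without S40 replicate 3 (−0.60).

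Among the fixed lists in XL40 vs S40, 12 of 20 inflammatory genes were higher, and 14 when adjusted over the list alone. Their median was 1.60, or 1.36 with genes below background at their bound and 1.07 without background correction (adjusted p = 4.29e-34, adjusted p = 0.00446 with an estimated correlation). Interferon genes had 10 of 22 higher, 16 adjusted over the list alone, and a median of 1.01, or 0.82 at the bound and 0.45 without background correction (adjusted p = 1.66e-24). Of the immediate early genes 1 was higher and 3 were lower, 1 and 7 adjusted over the list alone, with a median of −0.35, or −0.23 at the bound and −0.22 without background correction (adjusted p = 3.99e-06). Genes of p53 and apoptosis had a median of 0.21, or 0.11 at the bound, with 2 of 15 higher, 3 adjusted over the list alone (adjusted p = 0.00454, adjusted p = 0.0189 with an estimated correlation). The cell cycle median of −0.25 did not hold (adjusted p = 0.000767, adjusted p = 0.478 with an estimated correlation), with 1 gene lower adjusted over the list alone. Across all genes, 109 were higher and 9 lower, of which 74 and 2 changed more than 2-fold. The count of 118 was 72 without XL40 replicate 2.

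Cross-linked Aβ42 oligomers raised the same kind of genes. Against S42, Ccl20 rose by 4.61 ± 0.52 (adjusted p = 0.000154), Lcn2 by 4.29 ± 0.35 (adjusted p = 1.94e-06), Cfb by 4.0 ± 0.46 (adjusted p = 0.000154), Cxcl1 by 3.16 ± 0.46 (adjusted p = 0.00258) and Ccl2 by 2.79 ± 0.44 (adjusted p = 0.00607). Mmp3 rose by at least 5.17-fold, the chemokine Ccl5 by at least 4.56-fold and the interferon-induced chemokine Cxcl10 by at least 3.02-fold. Chi3l1, a secreted glycoprotein that reactive astrocytes make, rose by 1.79 ± 0.29 (adjusted p = 0.00684), and the iron carrier Tf by 1.73 ± 0.21 (adjusted p = 0.000213). Fos fell by 1.28 ± 0.22 (adjusted p = 0.01), Egr1 by 0.93 ± 0.17 (adjusted p = 0.0155) and Egr2 by 0.83 ± 0.14 (adjusted p = 0.01). Apart from Ccl20, Lcn2, Cfb and Tf, each of these calls was lost when single arrays were left out, though no change reversed. Without XL42 replicate 2, Ccl2 stood at 2.40, Cxcl1 at 2.83 and Chi3l1 at 1.45, and without S42 replicate 3 at 2.33, 3.06 and 1.70. Fos, Egr1, Egr2, Mmp3 and Cxcl10 lost their calls without any one of XL42 replicate 2, XL42 replicate 3, S42 replicate 1 or S42 replicate 3, with Egr1 between −1.09 and −0.78. Ccl5 and Chi3l1 lost theirs without XL42 replicate 2, S42 replicate 1 or S42 replicate 3, and Ccl2 and Cxcl1 without XL42 replicate 2 or S42 replicate 3.

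In XL42 vs S42, 15 genes were higher and 3 lower, and every one of the 3 that were lower was lower in XL40 vs S40 as well, a comparison with other arrays. Of the 15 higher, 14 were also higher there, where 0.177 were expected if the calls were independent. Inflammatory genes had 6 of 20 higher, 12 adjusted over the list alone, and a median of 1.05, or 0.85 at the bound and 0.63 without background correction (adjusted p = 4.83e-30, adjusted p = 0.00608 with an estimated correlation). Interferon genes, with the proteasome subunit Psmb8 at 1.21 ± 0.22 (adjusted p = 0.0181), had a median of 0.50, or 0.42 at the bound and 0.24 without background correction (adjusted p = 2.37e-09, adjusted p = 0.0839 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower. Immediate early genes had a median of −0.30, or −0.19 both at the bound and without background correction (adjusted p = 1.23e-09, adjusted p = 0.00115 with an estimated correlation), with 4 lower adjusted over the list alone. Small medians were called for Nrf2 genes of oxidative stress, 0.09 (adjusted p = 0.0101, adjusted p = 0.032 with an estimated correlation), and for p53 and apoptosis, 0.19 (adjusted p = 0.0295, adjusted p = 0.0638 with an estimated correlation). Psmb8 was lost without any one of the arrays named next. The count of 18 rested on single arrays, being 4 without XL42 replicate 2, 9 without XL42 replicate 3, 6 without S42 replicate 1 and 4 without S42 replicate 3.

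Inflammatory genes were higher also where untreated neurons or low molecular weight Aβ served as the reference. Ccl20 rose by 5.98 ± 0.42 and Lcn2 by 5.56 ± 0.29 in XL40 vs control, and by 6.17 ± 0.42 and 5.45 ± 0.29 in XL40 vs T40. In XL42 vs T42, Ccl20 rose by 4.30 ± 0.47 and Lcn2 by 4.12 ± 0.32. The neuropeptide gene Npy fell by 0.71 ± 0.16 in XL40 vs T40 (adjusted p = 0.0321), and the mitotic motor gene Kif11 by 0.75 ± 0.18 in XL40 vs control, where its other probe changed by only −0.17 and did not pass. The inflammatory medians were 1.27 in XL40 vs control, 0.73 in XL42 vs control, 1.45 in XL40 vs T40 and 0.88 in XL42 vs T42, each called also with an estimated correlation (highest adjusted p = 0.0472). Without background correction they were 0.71, 0.40, 0.81 and 0.53. Interferon genes in XL42 vs T42 had a median of 0.39 (adjusted p = 3.08e-10, adjusted p = 0.103 with an estimated correlation). Immediate early genes had a median of −0.39 in XL40 vs control (adjusted p = 0.00266) and −0.39 in XL42 vs control (adjusted p = 1.33e-10), or −0.22 and −0.26 without background correction. Npy was not called without any one of T40 replicate 1 (−0.67), T40 replicate 3 (−0.59), XL40 replicate 1 (−0.67) or XL40 replicate 2 (−0.73), and Kif11 kept its call only without XL40 replicate 3.

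Counts for these cross-linked groups leaned on single arrays. In XL40 vs control, 95 genes were higher and 21 lower, a count of 116 that was 71 without control replicate 1, 64 without XL40 replicate 2 and 211 without XL40 replicate 3. In XL40 vs T40, 112 were higher and 10 lower, a count of 122 that was 78 without T40 replicate 1, 291 without T40 replicate 2, 69 without XL40 replicate 2 and 362 without XL40 replicate 3. In XL42 vs control, 15 genes were higher and 1, Egr2, was lower (−0.75 ± 0.13, adjusted p = 0.00972). The call of Egr2 was lost without any one of control replicate 1 (−0.72), control replicate 3 (−0.72), XL42 replicate 2 (−0.81) or XL42 replicate 3 (−0.70). That count of 16 was 7 without XL42 replicate 2 and 9 without XL42 replicate 3. In XL42 vs T42, 19 genes were higher and none lower, and 8 passed without XL42 replicate 2.

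**Figure D2:**
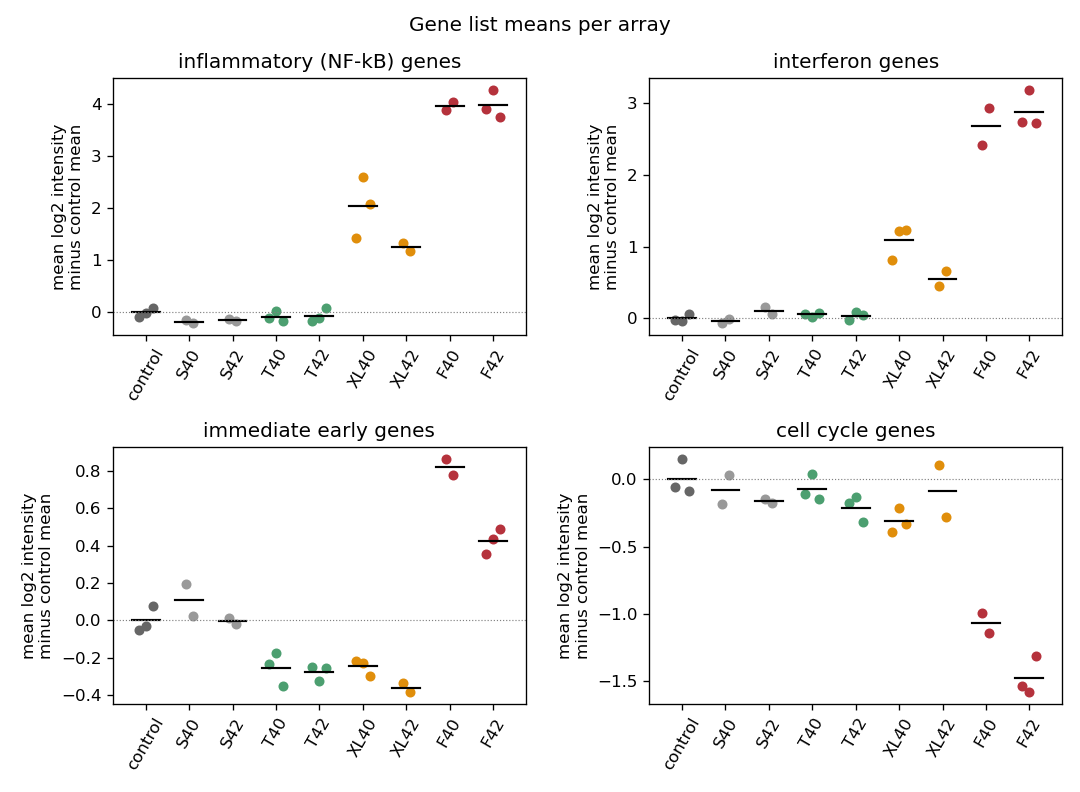
Mean log2 intensity of the inflammatory, interferon, immediate early and cell cycle lists minus the control mean, with 1 point per array and a bar at the group mean. Inflammatory genes lie at 3.96 with F40 and 3.98 with F42, at 2.03 with XL40 and 1.26 with XL42, and at −0.18 with S40.

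Aβ40 fibrils raised inflammatory and interferon-induced genes further and lowered genes of cell division. Against S40, Ccl20 rose by 8.52 ± 0.52 (adjusted p = 5.37e-10), the T-cell chemokine Ccl5 by 7.92 ± 0.44 (adjusted p = 2.09e-10), Cxcl1 by 7.51 ± 0.46 (adjusted p = 5.28e-10) and Lcn2 by 6.96 ± 0.35 (adjusted p = 7.59e-11). Genes below background with S40 rose by at least 200-fold (Cfb), 190-fold (Mmp3), 153-fold (Ccl7), 76.7-fold (Cxcl10), 44-fold (Cxcl11) and 25.6-fold (Ifit1). Mx1 rose by 5.01 ± 0.40 (adjusted p = 3e-08) and Irf7, the transcription factor that amplifies interferon production, by 4.68 ± 0.45 (adjusted p = 3.5e-07). Among genes of mitosis, the mitotic kinase Pbk fell by 1.73 ± 0.20 (adjusted p = 3.5e-06), cyclin Ccna2 by 1.72 ± 0.20 (adjusted p = 5.59e-06) and Pimreg by 1.88 ± 0.25 (adjusted p = 2.02e-05). Nkain4, a partner of the sodium pump, fell by 1.79 ± 0.19 (adjusted p = 1.29e-06). Where low molecular weight and cross-linked Aβ had lowered the immediate early genes as a group, F40 fibrils raised them, with Junb up by 2.60 ± 0.15 (adjusted p = 3.7e-10), Npas4 by 1.39 ± 0.22 (adjusted p = 0.000216) and Fos by 0.85 ± 0.22 (adjusted p = 0.0189). The call of Fos was lost without F40 replicate 1 (0.79), F40 replicate 2 (0.90) or S40 replicate 3 (0.60).

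Single stress and defence genes rose in F40 vs S40 without a call for their lists that held. Sod2 rose by 2.85 ± 0.21 (adjusted p = 1.23e-08) and the heme-degrading enzyme Hmox1 by 1.10 ± 0.24 (adjusted p = 0.00466). Phlda3 rose by 1.87 ± 0.18 (adjusted p = 3.69e-07), and Ddit3, which drives cell death under endoplasmic reticulum stress, by 1.04 ± 0.23 (adjusted p = 0.00493). The rise of Ddit3 rested on S40 replicate 1: without it Ddit3 stood at 0.55 and did not pass (adjusted p = 0.176), and against control it was at 0.44 (adjusted p = 0.299). Hmox1 was not called without F40 replicate 1 (1.03) or S40 replicate 1 (0.99). Inflammatory genes had 18 of 20 higher, 18 adjusted over the list alone, and a median of 2.92 (adjusted p = 3.48e-40). Interferon genes had 19 of 22 higher, 20 adjusted over the list alone, and a median of 2.73, or 1.79 without background correction (adjusted p = 2.3e-37). Immediate early genes had 9 of 16 higher, 10 adjusted over the list alone, and a median of 0.64 (adjusted p = 2.17e-08). Cell cycle genes had 15 of 20 lower, 18 adjusted over the list alone, and a median of −1.0 (adjusted p = 2.98e-16, adjusted p = 0.0115 with an estimated correlation). Vascular and fibroblast markers had a list mean relative to control of −0.43 with F40 and −0.23 with S40. Cholesterol synthesis genes had a median of −0.29 with 3 of 17 lower, 6 adjusted over the list alone (adjusted p = 2e-04, adjusted p = 0.0456 with an estimated correlation). The median of 0.24 for unfolded protein response genes did not hold (adjusted p = 0.0442, adjusted p = 0.522 with an estimated correlation). Genes of p53 and apoptosis had 4 of 15 higher, 6 adjusted over the list alone, but a median of 0.05 and a mean of 0.40 (adjusted p = 0.0545). Nrf2 genes had 4 of 19 higher and a median of 0.05 (adjusted p = 0.058), and heat shock genes a median of 0.06 (adjusted p = 0.691). Relative to control, the list means with F40 were 0.31 (SD 0.02) for Nrf2 genes and 0.37 (SD 0.06) for p53 and apoptosis genes. The Nrf2 list was called in F40 vs T40 at the preset correlation.

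In all, F40 vs S40 had 427 genes higher and 263 lower, of which 285 and 124 changed more than 2-fold. The count of 690 was 441 without F40 replicate 1, 401 without F40 replicate 2, 392 without S40 replicate 1, and 1527, 923 higher and 604 lower, without S40 replicate 3. App, the gene of the Aβ precursor, did not pass (−0.12 ± 0.18, adjusted p = 0.754). Gfap, the filament protein of astrocytes, did not pass either at 0.02 ± 0.17 (adjusted p = 0.973), a sign that turned to −0.10 under median scaling, and to −0.04 both without S40 replicate 1 and with the 5 arrays high on the second component left out.

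Aβ42 fibrils moved the same groups of genes. Against S42, Ccl20 rose by 8.73 ± 0.47 (adjusted p = 9.06e-11), Cfb by 8.32 ± 0.42 (adjusted p = 2.94e-11), Ccl2 by 7.43 ± 0.40, Cxcl1 by 7.31 ± 0.42 and Lcn2 by 6.79 ± 0.32 (adjusted p = 1.57e-11). Genes below background with S42 rose by at least 281-fold (Ccl5), 210-fold (Mmp3), 175-fold (Ccl7), 55.7-fold (Cxcl11), 39.5-fold (the secreted phospholipase Pla2g2a) and 35.3-fold (Ifit1). Irf7 rose by 5.14 ± 0.41 (adjusted p = 1.81e-08) and Mx1 by 4.78 ± 0.37. Sostdc1, a secreted BMP and Wnt antagonist, fell by 3.05 ± 0.31 (adjusted p = 5.78e-07), Nkain4 by 2.65 ± 0.17 (adjusted p = 9.28e-10), and the angiotensinogen gene Agt, expressed in astrocytes, changed by −2.32 ± 0.45 (adjusted p = 0.00143). Cyclin Ccnb2 fell by 2.12 ± 0.21 (adjusted p = 4.04e-07) and the ribonucleotide reductase subunit Rrm2 by 2.01 ± 0.22. Junb rose by 2.86 ± 0.14 (adjusted p = 1.71e-11) and Fos by 0.83 ± 0.20 (adjusted p = 0.00839), whereas the small heat shock gene Cryab fell by 1.54 ± 0.22 (adjusted p = 4.93e-05). Fos was not called without S42 replicate 1 (0.88) or S42 replicate 3 (0.79).

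In F42 vs S42 the inflammatory list had 19 of 20 genes higher, 20 adjusted over the list alone, and a median of 3.24, or 3.03 at the bound and 2.30 without background correction (adjusted p = 2.8e-42, adjusted p = 0.00126 with an estimated correlation). The interferon list had 21 of 22 higher, 21 adjusted over the list alone, and a median of 2.72, or 2.53 at the bound and 1.73 without background correction (adjusted p = 5.93e-40). The cell cycle list had 16 of 20 lower, 17 adjusted over the list alone, and a median of −1.46, or −0.99 without background correction (adjusted p = 3.7e-20, adjusted p = 0.0064 with an estimated correlation). Immediate early genes had 4 of 16 higher, 5 adjusted over the list alone, and a median of 0.22, or 0.17 at the bound and 0.13 without background correction (adjusted p = 0.00386, adjusted p = 0.0461 with an estimated correlation). Genes of p53 and apoptosis had a median of 0.40, or 0.26 without background correction (adjusted p = 0.00325, adjusted p = 0.0136 with an estimated correlation). Phlda3 led these at 1.64 ± 0.16 (adjusted p = 4.83e-07), with the cell cycle inhibitor Cdkn1a at 1.23 ± 0.35 (adjusted p = 0.0311). Cdkn1a was not called without F42 replicate 1 (1.21), F42 replicate 2 (1.0) or S42 replicate 3 (0.89). The median of −0.21 for cholesterol synthesis genes did not hold (adjusted p = 0.0127, adjusted p = 0.19 with an estimated correlation). In all, 454 genes were higher and 405 lower, of which 281 and 155 changed more than 2-fold. The balance turned with scaling, from 52.9% higher to 46.7% higher under median scaling. The count of 859 was 519 without S42 replicate 1 and 551 without S42 replicate 3.

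In F42 vs S42 no list of cell type markers was called as a whole, though single members passed, among them 4 of the 11 microglia markers. Neuron markers had a median of 0.07 (adjusted p = 0.843), with the transcription factor Neurod2 up by 0.84 ± 0.19, a call lost without S42 replicate 1 (0.65). Astrocyte markers had a median of 0.00 (adjusted p = 0.878), while the calcium-binding protein S100b fell by 1.20 ± 0.30 (adjusted p = 0.0126) and the glycolytic enzyme Aldoc fell by 1.04 ± 0.20 (adjusted p = 0.0013). S100b was not called without F42 replicate 2 (−1.04) or S42 replicate 1 (−1.02). Of the microglia markers 4 were higher, against 454 of all 9258 genes: the protease Ctss by at least 3.93-fold, the invariant chain Cd74 by at least 2.58-fold, the lectin Lgals3 by 1.14 ± 0.15 (adjusted p = 1.64e-05) and the receptor Cd14 by 0.92 ± 0.19 (adjusted p = 0.00229). These 4 passed with any single array left out, and the list had a mean of 0.35 and a median of −0.05, or 0.00 at the bound (adjusted p = 0.087). Trem2 was called lower but lay below background with F42, and its call was lost without F42 replicate 2, F42 replicate 3 or S42 replicate 3. Oligodendrocyte lineage markers had a median of −0.17 (adjusted p = 0.878), with Enpp2 up by 1.51 ± 0.17. Vascular and fibroblast markers had a median of −0.38 (adjusted p = 0.087), with the collagen gene Col1a2 at −0.97 ± 0.16. App at −0.15 ± 0.16 (adjusted p = 0.626), Gfap at −0.15 ± 0.15 (adjusted p = 0.595), Aif1 at −0.48 ± 0.58 (adjusted p = 0.664) and Hmox1 at 0.30 ± 0.22 (adjusted p = 0.431) did not pass. Synaptic genes had a median of 0.00, amyloid and tau genes −0.10, glycolysis and hypoxia genes −0.07, lysosome and autophagy genes −0.01, oxidative phosphorylation genes 0.00, proteasome genes 0.07 and ribosomal protein genes −0.05 (adjusted p = 0.878 for each). Heat shock genes at −0.10 and unfolded protein response genes at 0.07 (adjusted p = 0.703 for both), and Nrf2 genes at 0.06 (adjusted p = 0.255), were not called either.

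**Figure D3:**
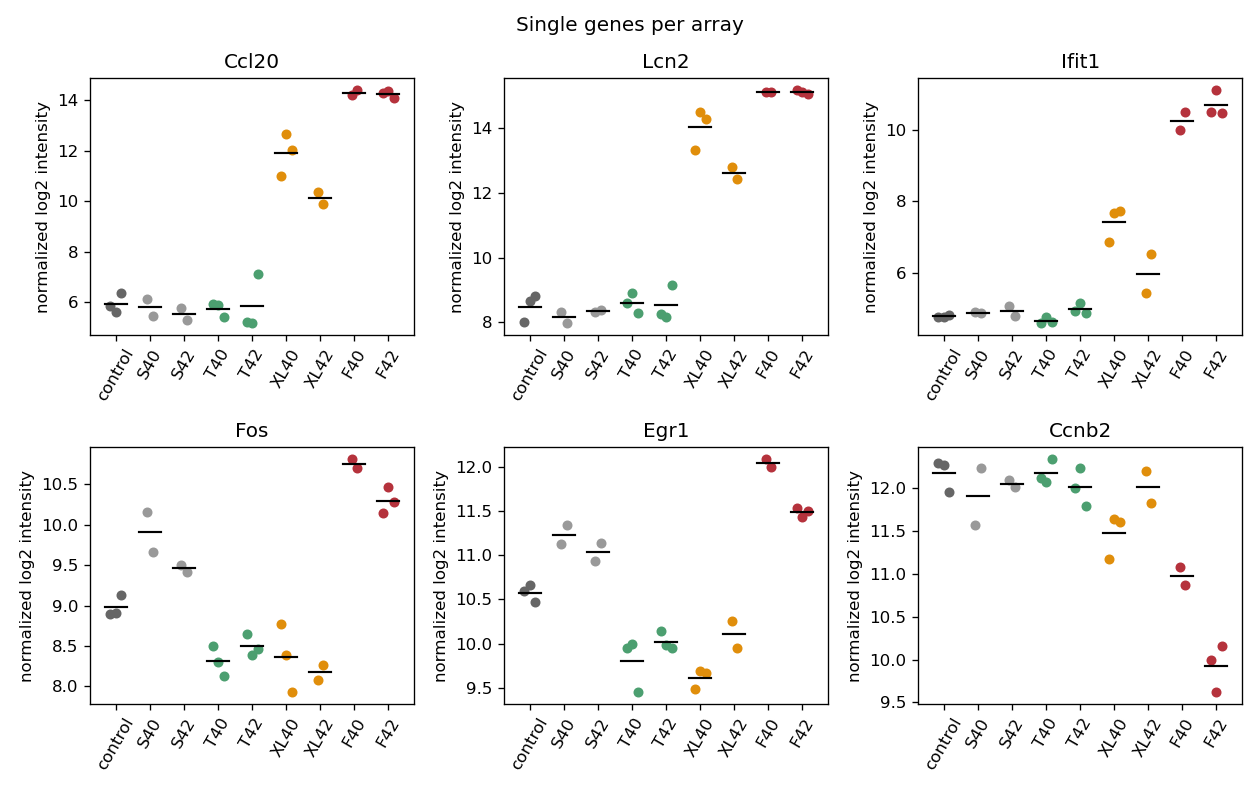
Normalized log2 intensity of Ccl20, Lcn2, Ifit1, Fos, Egr1 and Ccnb2, with 1 point per array and a bar at the group mean. Lcn2 has a mean of 8.48 in control and 15.13 with F42 fibrils, and Ccl20 means of 5.94 and 14.26.

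Fibrils against untreated neurons and against low molecular weight Aβ gave the same main groups. With F42 against control, Ccl20 rose by 8.32 ± 0.42, Lcn2 by 6.65 ± 0.29 (adjusted p = 2.2e-12), and RT1-Da, a class II molecule of antigen presentation, by at least 46.9-fold. Knstrn, a kinetochore gene, fell by 2.30 ± 0.17, and Lox, which cross-links collagen, by 2.25 ± 0.27. With F40 against control, Lcn2 rose by 6.63 ± 0.32, and Sostdc1 fell by 2.26 ± 0.31. Cell cycle medians were −1.14 in F40 vs control, −1.59 in F42 vs control, −1.0 in F40 vs T40 and −1.44 in F42 vs T42, each called also with an estimated correlation (highest adjusted p = 0.00977). Without background correction these were −0.91, −1.10, −0.77 and −0.94. Inflammatory medians were 2.89, 2.87, 2.87 and 2.95 in that order. Immediate early genes were higher in all 4 of these comparisons, with a lowest median of 0.10 in F42 vs control, where their mean was 0.43 (adjusted p = 0.00222, adjusted p = 0.0353 with an estimated correlation). Vascular and fibroblast markers had a median of −0.58 in F42 vs control (adjusted p = 0.00493, adjusted p = 0.282 with an estimated correlation) and microglia markers one of −0.04 in F42 vs T42, or −0.26 with median scaling and 0.00 at the bound, with a mean of 0.48 and 4 of 11 higher (adjusted p = 0.0252, adjusted p = 0.234 with an estimated correlation).

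By count, F40 vs control had 367 genes higher and 315 lower, F42 vs control 519 and 588, F40 vs T40 374 and 307, and F42 vs T42 705 and 776. In F42 vs T42, 47.6% of the genes called were higher, and 38.3% under median scaling. The F40 vs control count of 682 was 413 without F40 replicate 2, and the F40 vs T40 count of 681 was 445 without F40 replicate 1 and 398 without F40 replicate 2. The F42 vs T42 count of 1481 was 969 without T42 replicate 1.

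Few genes passed between the peptide lengths within one assembly. F42 fibrils gave more Cxcl13, a B-cell chemokine, than F40 fibrils (1.3 ± 0.16, adjusted p = 0.00114), more Cd74 (0.97 ± 0.15, adjusted p = 0.0157), and at least 1.49-fold more of the carboxylesterase Cesl1. The activity-dependent transcription factor Npas4 was lower by −1.53 ± 0.20 (adjusted p = 0.00174) and the costimulatory receptor Cd40 by −0.84 ± 0.14 (adjusted p = 0.0336). Immediate early genes as a list were lower with F42 (median −0.45, adjusted p = 8.06e-07, adjusted p = 0.00527 with an estimated correlation), and 8 were lower adjusted over the list alone. The cell cycle median of −0.45, or −0.24 without background correction, did not hold (adjusted p = 8.57e-07, adjusted p = 0.334 with an estimated correlation). In XL42 vs XL40, Ccl7 was lower by −2.21 ± 0.37 and Ccl19 by −1.63 ± 0.27 (adjusted p = 0.0293 for both), and Tnfrsf18 was at least 1.17-fold higher (adjusted p = 0.0184). Inflammatory genes in XL42 vs XL40 had a median of −0.53 and interferon genes one of −0.43 (adjusted p = 4.72e-08 and adjusted p = 0.433 with an estimated correlation for both), or −0.29 and −0.22 without background correction. For T42 vs T40, 0 genes passed by limma, with 745 at an unadjusted p under 0.05, and Tmem229b at −0.89 was among those of smallest p (adjusted p = 0.145).

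These 5 genes for fibrils and 3 for oligomers depended on single arrays and on scaling. For Cxcl13 and the other genes of F42 vs F40 the count was 1 without F40 replicate 1, 2 without F42 replicate 2 and 8 without F42 replicate 3, and under median scaling it was 2, of which 0% were higher. For Ccl7, Ccl19 and Tnfrsf18 in XL42 vs XL40 it was 40 without XL40 replicate 1, 0 without XL40 replicate 2, 5 without XL40 replicate 3 and 0 without XL42 replicate 2. T42 vs T40 gave 9 without T42 replicate 2. A direct test of whether the effect against scrambled peptide differed between lengths gave 0 genes by limma for each assembly. At an unadjusted p under 0.05 there were 687 for the low molecular weight, 354 for the cross-linked and 1679 for the fibrillar preparations (smallest adjusted p = 0.455, adjusted p = 0.579 and adjusted p = 0.195).

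Over the mean of the 6 Aβ groups against the mean of the scrambled groups, the genes whose arrays did not overlap were 4. They were the drug efflux pump Abcb1b (1.83 ± 0.15, adjusted p = 6.73e-08), Phlda3 (1.03 ± 0.10, adjusted p = 1.03e-06), the peptide transporter Tap1 (0.99 ± 0.15, adjusted p = 0.000189) and Rnaseh1 (0.37 ± 0.07, adjusted p = 0.00227). Egr1 fell by 0.62 ± 0.10 (adjusted p = 0.000222) and Fos by 0.62 ± 0.12 (adjusted p = 0.00352) on this mean, over groups in which they went both ways, and Fos was not called without S40 replicate 1 (−0.49). Inflammatory genes had a median of 1.52 with 17 higher, interferon genes 1.22 with 16 higher (0.72 without background correction), and cell cycle genes −0.45 with 9 lower (adjusted p = 2.95e-15, adjusted p = 0.0196 with an estimated correlation). In all, 284 genes were higher and 79 lower, a count of 363 that was 241 without S42 replicate 3.

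The fibril effects of both lengths, which share no arrays, overlapped closely. Of the genes higher with F40 against S40, 303 were also higher with F42 against S42, with 20.9 expected if the calls were independent. Of those lower, 126 were shared, with 11.5 expected, and 1 gene in each direction was called with the opposite sign. Across genes, which are not independent replicates, the log2 fold changes had r = 0.68. Of the 95 genes higher in XL40 vs control, 86 were higher in F40 vs S40 (4.38 expected), led by Ccl20 and Lcn2. Of the 21 that fell there, which include Egr1, 2 fell with F40 (0.597 expected, one-sided Fisher's exact test p = 0.119), 3 were called with the opposite sign, and 10 had the same sign whether called or not.

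**Figure D4:**
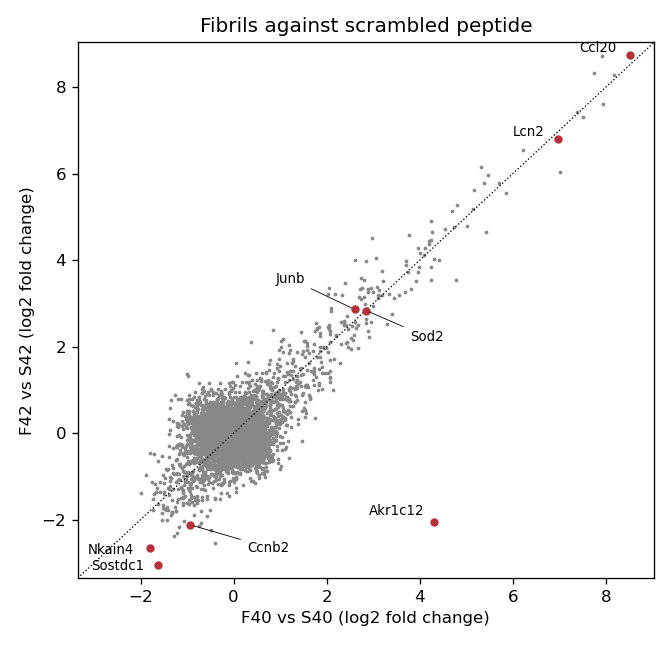
Log2 fold change of each gene in F42 vs S42 against that in F40 vs S40. Genes called with the same sign in both, 303 higher and 126 lower, lie along the diagonal.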

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

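The tests weighed in this part were chosen after the results were seen, except the counts over other splits of the samples, which were planned. In the direct test, no single gene passed for a difference between lengths in its effect against scrambled peptide.

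Signal appeared on probes that the platform assigns to no gene, which the comparisons of genes did not use. Of 4065 such probes above background, 183 were called in F42 vs S42, 99 higher and 84 lower. By limma, 0 were called in S40 vs control and 0 in S42 vs control. The largest rise was on the unnamed probe ILMN_1357368, with a log2 fold change of 6.42 ± 0.24. No explanation was tested for these probes, since the files give neither their genes nor their sequences.

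The rise of inflammatory genes with fibrils was weighed first. If more microglia, each with unchanged expression, had been the whole cause, their markers would have risen by about as much. In F42 vs control, all 11 microglia markers tested had a median of −0.04, or 0.00 with genes below background at their bound, below the inflammatory median of 2.87 by more than their SD of 1.04. The 4 detected on every control array were Fcer1g (−0.80), Cd14 (0.55), Gpnmb (0.25) and Lgals3 (0.97), with a median of 0.40 and an SD of 0.75. Of those below background in control, Ctss rose by at least 3.81-fold and Cd74 by at least 2.5-fold, while C1qb did not pass (adjusted p = 0.624). The medians of −0.04 and 0.40 argue against more microglia of unchanged expression as the whole cause. Markers not detected on every control array lay near background there, so they weigh a change in number only weakly. A change within microglia stays open, as does some rise in their number, since 4 of the 11 markers were higher in F42 vs S42. Other cells of the culture as the source were not tested. Astrocyte markers such as Gfap were bright in control (mean log2 14.63). Quantile normalization is argued against as well, since the inflammatory median in F42 vs S42 was 3.22 with median scaling and 3.24 without. A contaminant carried by the cross-linked and fibrillar preparations stays open. The low molecular weight preparations left the list at or below −0.05 against control, but contaminant and assembly go together in this design and cannot be told apart. A response of the cultures to assembled Aβ is the biological explanation the groups name, and it may be the cause, but it stays untested against that contaminant.

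The fall of cell cycle genes with fibrils was weighed second. Hippocampal neurons do not divide, so these transcripts may come from other cells of the culture. A loss of astrocytes in general, as large as the cell cycle fall, is argued against. Astrocyte markers had a median of 0.01 in F42 vs control (SD 0.53, 14 genes) against −1.59 for the cell cycle genes. A loss of only the dividing astrocytes could leave these markers flat, so the median does not weigh it. Vascular and fibroblast markers had a median of −0.58 (SD across genes 0.54, 11 genes), short of the cell cycle fall by more than this SD. By limma 5 of them were lower and 0 higher, against 588 lower and 519 higher of all 9258 genes. A loss of such cells could therefore be a part. Whether it is the whole was not decided, since a loss of only the dividing ones could lower the markers less. The list mean of these markers relative to control was −0.57 with F42 and −0.43 with F40, against −0.19 with S42 and −0.23 with S40. The brightest of these markers in control, Igfbp2 (14.59), Col1a2 (13.71) and Tagln (11.77), changed by −0.68, −1.13 and −1.59, so that Tagln alone fell as far as the cell cycle median. The brightest astrocyte markers, Fabp7 (15.13) and Gfap (14.63), changed by 0.02 and −0.10, but lie near the brightest probes, where a change may be understated. Of the 14 astrocyte markers, 3 passed as lower in F42 vs control: Aldoc (−0.86), Fgfr3 (−0.65) and Mlc1 (−0.50). Another 2 passed as higher, Acsbg1 (0.97) and Slc1a2 (0.64). Each of these genes was detected on 23 of 23 arrays, so the cultures hold such transcripts without Aβ. Median scaling gave −1.47 in F42 vs S42 against −1.46, which argues against the normalization. Slower division of cells that remained stays open, as does the loss of dividing cells, whether of a type on the lists or not.

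The gap between S40 replicates 1 and 3, the pair with the lowest correlation in a group, was weighed last. Without S40 replicate 3, S40 vs control gave 450 genes in place of 0. An array of a cross-linked or fibril group under the wrong label is argued against, since the inflammatory mean of S40 replicate 1 was −0.15 from control, while the lowest of those arrays had 1.18 (SD of the control arrays 0.09). Array brightness did not decide: across 23 arrays, deviations within groups on the leading axis had r = −0.13 with mean raw intensity (permutation p = 0.67, rho = −0.12 with permutation p = 0.67, r = −0.20 without the 2 farthest arrays). With the number of probes detected, the same deviations had r = 0.87 (permutation p = 0.00013, rho = 0.85 with permutation p = 0.00014, r = 0.90 without the 2 farthest arrays), and the Benjamini-Hochberg p over the 2 relations was 0.00026. The number of probes detected comes from the same intensities as the axis. This relation therefore cannot tell labelling or hybridization that differed between arrays from a difference between cultures. Both stay open, and no slide or date is given in the sources used here that would test them further.

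Other splits of the same arrays were counted for each comparison of at least 3 arrays a side. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Where the real count is 0, every split gives at least as many, so the counting decides nothing. This holds for T40 vs control (10 of 10, highest other 0), T42 vs T40 (10 of 10, highest other 1) and the mean of the scrambled groups against control (35 of 35, highest other 0). In XL40 vs control 1 split, the real one, gave as many as its 116 genes (highest other 0). This number was also 1 for T42 vs control (1 gene, highest other 0), F42 vs control (1107, highest other 0), XL40 vs T40 (122, highest other 3) and F42 vs T42 (1481, highest other 0). For the mean of the 6 Aβ groups, 2 of 100 orders of the labels, the real one included, gave as many as 363 genes. The other orders mixed treatments within groups, which widens the spread per gene and lowers the counts. This share therefore does not decide whether Aβ differs from scrambled peptide. The highest other order gave 446 from a regrouping of the same arrays.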

How the results depend on the processing

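Of the alternatives in this part, leaving out the arrays above 10 on the second principal component was the only one chosen after the data were seen. Counts are genes past the threshold. For settings that change the processing, the cause was not tested. With only the groups compared in the fit, and with arrays left out, fewer arrays and fewer residual degrees of freedom remain.

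Without background correction, and equally with the values normalized by the authors, T42 vs S42 gave 2, T40 vs control 1, T42 vs control 11, XL42 vs XL40 12 and F42 vs F40 3. With median scaling, XL42 vs XL40 gave 0 and F42 vs F40 2. Without a detection filter, XL42 vs XL40 gave 1 and F42 vs F40 12, and with the stricter filter F42 vs F40 gave 2. With the replicate number as a block, XL42 vs XL40 gave 14 and F42 vs F40 9. As a check of pairing, 77 pairs of arrays with the same number were correlated after group means were removed. The correlations ran from −0.31 to 0.54, with 20 above 0.1. Their median was 0.02, against −0.01 for pairs with different numbers, and 11 of 23 arrays matched their own number best. These values do not decide whether the numbers pair the arrays. A slide block was not run because the files name no slides. With an estimated correlation, 62 of the 94 list calls held.

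With only the groups compared in the fit, T40 vs S40 gave 0, XL40 vs S40 22, F40 vs S40 282, T42 vs S42 0, XL42 vs S42 7, XL40 vs control 64, T42 vs control 0, XL42 vs XL40 0, F42 vs F40 0, XL40 vs T40 51 and XL42 vs T42 11. With 5 arrays high on the second component left out, XL40 vs S40 gave 65, of which 59 were among its 118, T42 vs S42 3, XL42 vs S42 31, XL40 vs control 73, T42 vs control 9, XL42 vs control 42, XL42 vs XL40 15 and XL42 vs T42 51. F42 vs S42 gave 902, F40 vs S40 470 and S40 vs control 0, within 1.5 times of their counts.

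With single arrays left out, the counts ran from 0 to 450 in S40 vs control, 0 to 0 in S42 vs control and T40 vs control, 64 to 211 in XL40 vs control, 413 to 603 in F40 vs control, 0 to 2 in T42 vs control, 7 to 14 in XL42 vs control, 795 to 1024 in F42 vs control and 0 to 1 for the mean of S40 and S42 vs control. They ran from 1 to 621 in T40 vs S40, 0 to 2 in T42 vs S42, 72 to 129 in XL40 vs S40, 4 to 9 in XL42 vs S42, 392 to 1527 in F40 vs S40 and 519 to 767 in F42 vs S42. They ran from 69 to 362 in XL40 vs T40, 8 to 24 in XL42 vs T42, 398 to 613 in F40 vs T40, 969 to 1462 in F42 vs T42, 0 to 9 in T42 vs T40, 0 to 40 in XL42 vs XL40 and 1 to 8 in F42 vs F40. The mean of the 6 Aβ groups gave 241 to 394 and the test of any difference 844 to 1905. Where one array was left in a group, it was assumed to vary like the other groups.

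Among values of named genes, none that was called reversed in 3965 gene results under processing settings, where 3652 stayed past the threshold and 313 did not, or in 3004 with an array left out, where 2488 stayed and 516 did not. Of the values not called, Gfap in F40 vs S40 was the only one that reversed, from 0.02 to −0.10 with median scaling, −0.04 with the second-component arrays left out and from −0.04 to 0.08 with single arrays left out, −0.04 being without S40 replicate 1. None of the 94 list medians changed sign under the scaling alternatives, but their size did change. More than 1.5 times smaller were 36 without background correction, 37 with the values normalized by the authors and 1 with median scaling, and 4 were more than 1.5 times larger with median scaling. These 4 were ribosomal protein genes in T40 vs S40 (−0.11 to −0.32) and XL40 vs T40 (0.12 to 0.20), Nrf2 genes in F40 vs T40 (0.11 to 0.26) and microglia markers in F42 vs T42 (−0.04 to −0.26). The 1 that shrank was Nrf2 genes in XL42 vs control (0.09 to 0.04). The interferon median went from 1.01 to 0.45 and 0.44 in XL40 vs S40, and from 3.02 to 1.64 and 1.63 in F42 vs control, in the order of the first 2 settings. Of 497 gene results called, 146 were more than 1.5 times smaller under each of these 2 settings. Intensity that is not subtracted compresses a fold by construction, so the bounds hold on the corrected scale only.

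Signal over background limits the genes that were silent without Aβ. Their rises are lower bounds, and 9 of the 20 inflammatory genes in F40 vs S40 lay below background with S40 or could not be given a fold. At the other end, Lcn2 reached a mean of 15.12 with F40 and 15.13 with F42, near the brightest probes of the arrays, so a further rise would be hard to see.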

Other observations

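The tests and values of this part were chosen after the results were seen.

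Whether cross-linked oligomers act like weaker fibrils was tested on separate arrays. Among 42 inflammatory and interferon genes, the changes in XL40 vs control and in F40 vs S40 had r = 0.90 across genes, which are not independent replicates, and 95.2% had the same sign, with a slope of 1.34. Both lists had already been called higher with XL40 and with F40 against scrambled peptide, so a shared sign was likely beforehand. The values therefore do not decide whether these genes show one response at different strengths. For the immediate early genes the list mean relative to control was −0.25 with XL40 and 0.82 with F40. These opposite signs argue against a weaker fibril response as the only effect of XL40. The mean was also −0.25 with T40 and −0.28 with T42. A fall shared with these groups could hide a weak fibril-like rise with XL40, which stays open. F40 vs XL40 had a median of 1.07 for this list (camera adjusted p = 4.16e-15, adjusted p = 0.000101 with an estimated correlation). In that comparison Egr1 was higher by 2.43 and Fos by 2.39, and against control Egr1 fell by 0.96 with XL40 (adjusted p = 0.000308). Junb went the other way: it rose by 0.77 with XL40 against control (adjusted p = 0.00115) and was higher by a further 2.03 in F40 vs XL40, as one response at different strengths would give. Dose was not given in the sources used here, so assembly and effective dose were not separated.

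Gene families defined by a shared symbol stem, 309 with at least 5 members, were tested with camera. The RT1 family of major histocompatibility genes, which present antigen, had 17 of 24 members higher in F42 vs S42, with a median of 2.44, or 2.29 with genes below background at their bound (adjusted p = 4.65e-26, adjusted p = 0.0318 with an estimated correlation). In F40 vs S40, 15 of the 24 were higher, with a median of 2.04, or 1.91 at the bound, a call that was lost with an estimated correlation (adjusted p = 3.96e-17, adjusted p = 0.0844 with an estimated correlation). RT1-A2, which was above background on every array, rose by 4.05 ± 0.33 in F42 vs S42. Members of this family resemble each other, and cross-hybridization between them was not tested because no probe sequences were at hand. In XL40 vs S40, 9 of the 24 were higher, with a median of 0.70, or 0.62 at the bound (adjusted p = 2.86e-14, adjusted p = 0.272 with an estimated correlation). The Cdca genes of cell division had 4 of 6 lower in F42 vs S42, with a median of −0.98 (adjusted p = 0.000121, adjusted p = 0.0318 with an estimated correlation). Genes with the Mcm stem, among them subunits of the replicative helicase, had 6 of 9 lower, with a median of −1.03 (adjusted p = 4.4e-05, adjusted p = 0.132 with an estimated correlation), and Mcm3 fell by 1.61. Lgals3bp, a secreted glycoprotein that interferon induces, rose by 3.22 ± 0.28.

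A single gene varied within groups far more than any other. The probe of Akr1c12, an aldo-keto reductase, had a residual SD of 2.10, against a median of 0.22 over genes. It read 4.92 on S40 replicate 1, 7.45 on XL40 replicate 2, 7.65 on XL40 replicate 1 and 8.89 on F42 replicate 2, and from 11.64 to 13.88 on the other arrays. The arrays with these low readings are among the 5 above 10 on the second principal component. Other genes moved on the same arrays. In the order S40 replicate 1, XL40 replicate 2, XL40 replicate 1 and F42 replicate 2, Mtch1 read 9.43, 9.47, 10.42 and 10.44, against 11.75 on S40 replicate 3. Cox20 read 9.05, 8.75, 9.11 and 8.18 in that order, against 6.46 on S40 replicate 3.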
